A study of Mus musculus with 2 samples.

How the data were processed

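The series holds 2 single-cell RNA-seq libraries from mouse cerebral cortex dissociated with its meninges, 1 library from N-PRα-KO mice (Nestin-Cre with floxed Pdgfra) and 1 from WT mice (C57BL/6J). Per the labels' protocols, cells were enriched with magnetic beads against CD140a, the protein made from Pdgfra, and captured on the BD Rhapsody system with its whole-transcriptome kit. The labels give no age, sex or number of animals per library, so any difference in these between the libraries coincides with genotype.

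The deposited files hold raw counts of unique molecules (UMIs) per cell and gene. Per the file headers, the authors made these counts with the BD Rhapsody WTA Analysis Pipeline, version 1.10 for the N-PRα-KO library and 1.10.1 for the WT library, on GRCm38 with the GENCODE M19 annotation. The headers give different run dates for the 2 pipeline runs, so any processing or preparation batch coincides with genotype. The submitters' processing notes name the builds GRCm38 and mm10. The pipeline had already picked the barcodes it took for cells, per the file headers. The aligner is not given in the sources used here. Gene positions below were taken from GENCODE M21, another release on the same GRCm38 build.

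Cells with at least 300 genes and at most 25% mitochondrial UMIs were kept, and Scrublet calls (scanpy 1.11.5) were removed in each library. The filter kept 4196 of 8336 N-PRα-KO barcodes (50.3%) and 10069 of 11438 WT barcodes (88.0%), mostly because 4126 N-PRα-KO barcodes and 1329 WT barcodes failed the mitochondrial limit. Scrublet called 28 N-PRα-KO cells (0.667%) and 173 WT cells (1.72%), leaving 4168 and 9896 cells. Without the filter it called 1 of 8336 N-PRα-KO barcodes (0.012%), so it had not worked in that setting. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen per library and combined, and 30 components and 20 neighbours were used for Leiden clustering (leidenalg 0.10.2) at resolution 1, without integration of the libraries. This gave 33 clusters.

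Clusters were named from marker lists fixed before the data were examined. A name required a mean log2 fold of at least 0.5, a lead of at least 0.5 over the next class, at least 3 detected markers, and no more markers of another class than of its own among the top 10 genes by fold. A cluster with a median UMI count under its libraries' median divided by 3 and no own marker among those genes also stayed unnamed. The thresholds were set after the clusters were seen. The first rule took folds against all other cells and left cluster 18 unnamed, because Vtn, a pericyte marker, was among its top 10 genes and no fibroblast marker was. The rule was then changed, after this was seen, to folds against clusters whose best class was another, which named cluster 18 fibroblast-like. With each library clustered on its own, the first rule had also left many WT cells unnamed that the changed rule named. Values without cluster 18 were computed as an added alternative. Cluster 23 stayed unnamed because its arachnoid barrier score (1.39) led its fibroblast score (1.28) by too little, and cluster 29 because a marker of another class was among its top genes and none of its own.

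With 1 library per genotype no test was made. UMIs were summed per class and library, and CPM (a gene's UMIs scaled to the same class total in both libraries) carry exact Poisson 95% intervals, shares carry exact Clopper-Pearson 95% intervals, and log2 ratios carry exact conditional intervals. All of these cover counting error only, not variation between animals or preparations. Counts under 3 were set to 3 for ratios. Genes were named by a rule fixed before the data were examined: in fibroblast-like cells the 12 highest and 12 lowest log2 ratios among genes at 50 CPM or more in either library, in other classes with at least 50 cells in both libraries the 6 highest and 6 lowest, from each list the 4 members with the largest absolute ratio, and from each sub-cluster the 5 leading genes. Some genes that this rule names are not reported here. Mitochondrial, ribosomal protein, haemoglobin and predicted genes, Xist, Tsix and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were left out of that ranking. Genes over 3 times higher in another class of the same library were left out too. Other X-linked genes, such as Hs6st2 and Tceal1, stayed in the ranking. For gene lists, the median log2 ratio of members at 20 CPM or more was set against 10000 random lists of the same size matched on mean expression, as a description of these libraries. The interval of a list median came from 1000 Poisson draws of its members' counts. The listed genes Ccn2, Cfb, Clec7a and Pmp2 are under no such symbol in either table, and Ctgf, the older symbol of Ccn2, was used. Shares of cells with a UMI were also given after each cell was thinned to 2000 UMIs.

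Fibroblast-like cells were clustered again with 1000 variable genes, 20 components and resolution 0.5. After seeing that these sub-clusters parted by library, a clustering with each gene centred and scaled within each library was added, at resolutions 0.3 and 0.5. The relation of ratios to GC content was also examined only after the data were seen, with the GC content of the last 500 bases of each gene's longest transcript, of the whole transcript, and with transcript length. Of the 2 GC measures the first had the higher rank correlation with the ratio in all 8 classes and was used for a correction, in which the running median of the ratio over 20 GC bins was subtracted and the overall median restored. A correction for GC content of the whole transcript, lists limited to members over 3 times their level in other classes, values within library-centred sub-clusters and values without clusters 18 or 26 or without a sub-cluster led by oligodendrocyte precursor genes were further alternatives chosen after the data were seen. The alternatives planned before the data were examined were no cell filter, a stricter filter (at least 1000 genes and at most 10% mitochondrial UMIs), doublet calls kept, Leiden resolutions 0.5 and 2, each library clustered on its own, TMM scaling (edgeR 4.0.16 in R 4.3.3), the mean of per-cell CPM, thinned cells, mitochondrial and ribosomal genes left out of the total, list minimums of 5 and 100 CPM, and for sub-clusters resolutions 0.3 and 1 and variable genes without the members of the fixed lists.

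The ratio, list and GC steps were tested on simulated counts for the fibroblast comparison, with 200 changed genes. Over 6767 genes without a GC trend, genes set to log2 changes of 1 and 2 had median estimates of 1.02 and 1.98, and the intervals covered the truth for 95.2% of unchanged genes. With a GC trend added, over 7358 genes, coverage of unchanged genes was 32.1%, and the correction moved the medians for log2 changes of 1, 2, -1 and -2 from 1.12, 2.22, -1.16 and -1.955 to 1.01, 2.04, -1.01 and -2.06, the last of which was farther from the truth than before. Counting intervals therefore do not cover such a trend.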

Results

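The data were 2 libraries of CD140a-sorted cells from the mouse cerebral cortex with meninges, 1 from mice in which Pdgfra was floxed and Nestin-Cre was carried (N-PRα-KO) and 1 from WT mice. Nestin-Cre acts in the neural lineage, and Pdgfra encodes a receptor for platelet-derived growth factors found on oligodendrocyte precursors and fibroblasts. The series asks how heterogeneous activated fibroblasts are in the hypomyelinated cortex of these mice. The N-PRα-KO library held 41982217 UMIs in 8336 barcodes and the WT library 43459947 UMIs in 11438 barcodes. After filtering, the median cell had 5790.5 UMIs and 2406 genes in the N-PRα-KO library and 3284 UMIs and 1725 genes in the WT library. Y-linked genes had 3476 UMIs in the N-PRα-KO and 275 in the WT library, and Xist 15129 and 54754, so any difference in the sex of the animals coincides with genotype. Age is not given for either library, so a difference in age cannot be told apart from genotype in any comparison below. There was 1 library per genotype, so no difference below has a replicate check, and intervals are 95% and cover counting error only.

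The cell classes differed widely in share between the libraries. Oligodendrocyte-lineage-like cells were 1.61% of N-PRα-KO cells (67 of 4168, interval 1.25 to 2.04) and 51.1% of WT cells (5058 of 9896, interval 50.1 to 52.1). Fibroblast-like cells were 22.9% (953 cells, interval 21.6 to 24.2) against 5.17% (512 cells, interval 4.75 to 5.63). Endothelial-like cells were 12.9% against 3.51%, ependymal-like cells 11.9% against 3.52%, microglia-like cells 13.8% against 6.48%, mural-like cells 8.76% against 0.546% and border-macrophage-like cells 2.45% against 0.495%. Astrocyte-like cells were 16.03% against 18.4% and neuronal-lineage-like cells 6.29% against 9.66%. Choroid-plexus-like cells were 39 cells (0.936%) in the N-PRα-KO library and 1 cell (0.010%) in the WT library. Unnamed cluster 23 held 1.22% and 1.101% of cells and unnamed cluster 29 held 1.22% of N-PRα-KO cells and 0 of 9896 WT cells, which allows a share of up to 0.030% at 3 counts (exact upper limit 0.037%). These shares are of sorted cells and add up to a fixed total, so a class that is scarce in 1 library raises the shares of all others there, and the sort for CD140a and the mitochondrial limit can set them. Cluster 29 was led by Omp and other olfactory genes. Whether the same tissue was taken for both libraries was not tested, and a difference in it cannot be told apart from genotype.

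**Figure D1:**
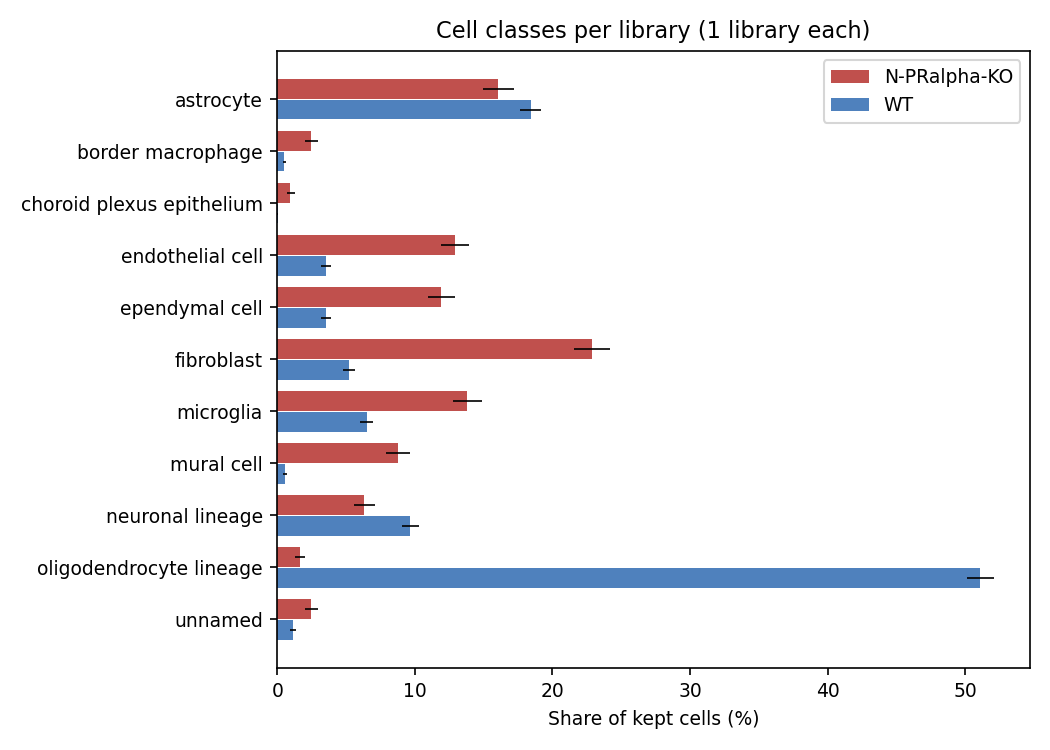
Share of kept cells (%, horizontal axis) in each cell class for the N-PRα-KO and WT libraries, with exact binomial 95% intervals as error bars. Oligodendrocyte-lineage-like cells reach 51.1% in the WT library and 1.61% in the N-PRα-KO library.

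Pdgfra (chromosome 5, 75152292 to 75198215, plus strand, GRCm38) was the targeted gene and also the antigen of the sort. In oligodendrocyte-lineage-like cells it stood at 1928 CPM (interval 1817 to 2043) in the N-PRα-KO library and 4633 CPM (4603 to 4664) in the WT library, a log2 ratio of -1.26. Without cluster 26, whose leading genes were myelin genes and which held 9 of the 67 N-PRα-KO and 144 of the 5058 WT cells, the values were 3228 and 4949 CPM and the log2 ratio was -0.62. In cluster 30, which held 45 N-PRα-KO cells and no WT cell, Pdgfra was at 3597 CPM and all 45 cells had a UMI. In fibroblast-like cells it was at 705 CPM (685 to 726) and 859 CPM (823 to 895), a log2 ratio of -0.28. With each library clustered on its own the log2 ratio became 0.01. The class then held 624 WT cells instead of 512 and 952 N-PRα-KO cells instead of 953, so this value may compare unlike cells. Which WT cells joined the class in that setting was not tested. Without cluster 18 the log2 ratio in fibroblast-like cells was -0.04. At sub-cluster resolution 1, 14 WT cells of this class (2.73%) and no N-PRα-KO cell formed a sub-cluster led by Lhfpl3, Cntn1, Ptprz1, Vxn and Ednrb, of which Lhfpl3 and Ptprz1 are on the OPC (oligodendrocyte precursor) identity list. It held 185 of the class's 2229 WT Pdgfra UMIs, at 1841 CPM, and without it, a choice made after the data were seen, the log2 ratio was -0.22. With cells thinned to 2000 UMIs, 64.7% of 948 N-PRα-KO and 76.8% of 469 WT fibroblast-like cells had a Pdgfra UMI, with 5 and 43 shallower cells left out. Unthinned, the shares were 89.3% and 90.4%, at median depths of 6225 and 4311 UMIs. Over the 6 other large classes Pdgfra lay between 22.8 and 61.4 CPM in the N-PRα-KO library and between 131 and 194 CPM in the WT library. In microglia-like cells, at median depths of 5602 and 2741 UMIs, 9.91% and 27.3% of cells had a UMI, and 3.84% and 19.4% once thinned. The fibroblast-like values were not corrected for this level in other classes, which was higher in the WT library. A lower Pdgfra level or thinned share in N-PRα-KO fibroblast-like cells can therefore not be told apart from it. The files do not say which exons the deletion removes, and counts from the 3′ end may fall outside it, so Pdgfra checks the genotype labels only in part.

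**Figure D2:**
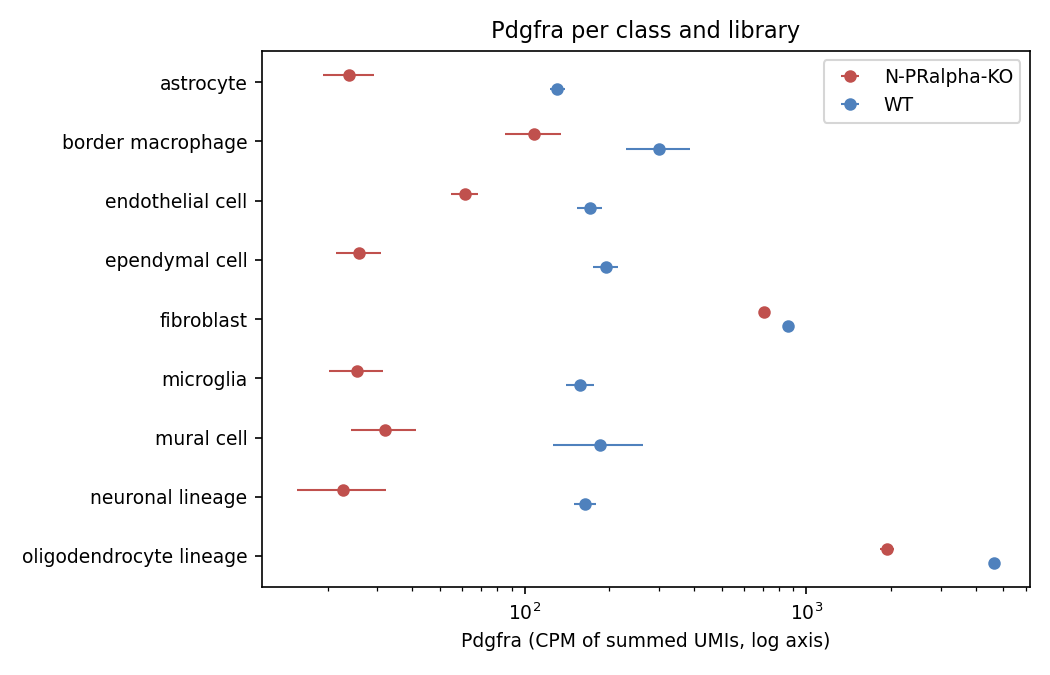
Pdgfra in CPM of summed UMIs (log axis) per cell class and library, with exact Poisson 95% intervals. Fibroblast-like and oligodendrocyte-lineage-like cells stand above all other classes in both libraries, and the other classes lie higher in the WT library.

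The ratios between the libraries followed base composition in every class compared. Across 7307 genes in fibroblast-like cells, the log2 ratio of N-PRα-KO over WT correlated with the GC content of the transcript's last 500 bases with a Spearman rho of 0.54, and across genes in the 7 other classes rho ran from 0.47 in mural-like cells to 0.65 in ependymal-like cells. Genes are not independent replicates. In fibroblast-like cells the fifth of genes poorest in GC had a median log2 ratio of -0.44 and the fifth richest in GC 0.85. Between the 28 pairs of the 8 classes, log2 ratios correlated across genes with Pearson's r of 0.56 to 0.89, and of 0.41 to 0.83 with the GC trend removed. In the parts on fibroblast-like, oligodendrocyte-lineage-like, microglia-like and endothelial-like cells, the median of a list is therefore first given as measured and with the GC trend removed.

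**Figure D3:**
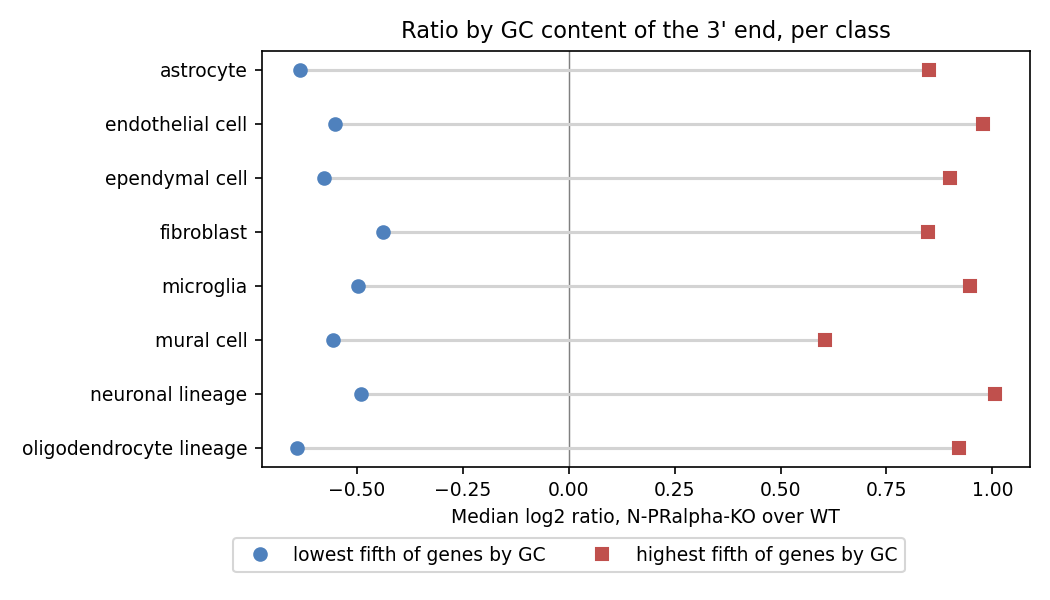
Median log2 ratio of N-PRα-KO over WT for the 20% of genes with the lowest and the 20% with the highest GC content in their last 500 bases, per cell class. The median is below 0 for the GC-poor genes and above 0 for the GC-rich genes in all 8 classes, from -0.44 to 0.85 in fibroblast-like cells.

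In fibroblast-like cells the N-PRα-KO library had lower levels of all measured immediate early and interferon-response genes and of 13 of 14 cell division genes. Different clusters held most of the class in the 2 libraries: clusters 6 (594 cells) and 18 (325 cells) in the N-PRα-KO library, and clusters 16 (366 cells) and 22 (132 cells) in the WT library. All 18 immediate early and dissociation genes were lower in the N-PRα-KO library, with a median log2 ratio of -2.10 (interval -2.20 to -2.02, percentile 0.0 of random lists) and -2.24 with the GC trend removed. Fos, an early-response transcription factor, was at 552 CPM against 4414 CPM, Atf3 at 13.3 against 244.6, Dusp1, a MAP kinase phosphatase, at 97.6 against 736 and Btg2 at 83.7 against 577. The same list was also below 0 in all 7 other classes, from -0.02 in oligodendrocyte-lineage-like cells, where 7 of 14 members were lower and the interval (-0.26 to 0.39) included 0, to -1.13 in neuronal-lineage-like cells, and from -0.03 to -1.30 in the same classes with the trend removed. All 7 measured interferon-response genes were lower, with a median of -1.41 (percentile 0.0) and -1.45 with the trend removed, and -2.27 without cluster 18, among them Ifit1 (4.53 against 31.6 CPM), Ifit3 (13.3 against 40.1), Irf1 (13.6 against 36.6) and Gbp2 (10.7 against 28.5). Within library-centred sub-cluster 1 the median was -0.93, but in library-centred sub-cluster 2, with 523 of the 953 N-PRα-KO cells, only 1 member reached the minimum level and it was higher, at 0.14. In the other classes where it was measured, that list's median ran from -0.25 to 0.54, and from -0.25 to 0.595 with the trend removed. Of 14 cell division genes, 13 were lower, with a median of -1.05 (percentile 0.0) and -0.94 with the trend removed, -0.57 without cluster 18 and -1.63 within library-centred sub-cluster 2, and the list was below 0 in all 8 classes with and without the GC trend. Cells led by division genes formed a library-centred sub-cluster apart from sub-cluster 2. None of the 14 genes stood over 3 times above its level in other classes of the same library. RNA from other cells can therefore not be told apart from a change in fibroblasts here. Hmmr was at 19.0 against 63.6 CPM, Cenpf at 29.6 against 75.1, Nusap1 at 20.9 against 51.2 and Rrm2 at 18.4 against 42.8.

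Of 13 BMP and Wnt signalling genes in fibroblast-like cells 9 were lower in the N-PRα-KO library, with a median log2 ratio of -0.85 (percentile 0.0) and -0.74 with the GC trend removed, and -0.42 and -0.56 within library-centred sub-clusters 1 and 2. Bmp2 was at 107 against 272 CPM, Sfrp1 at 55.0 against 156 and Wnt6 at 10.3 against 25.8, while Frzb, a secreted Wnt antagonist, was at 65.7 against 24.7. Of 10 measured genes on the chemokine and cytokine list, which also holds the adhesion genes Icam1 and Vcam1, 7 were lower, with a median of -0.97 (percentile 0.1) and -0.86 with the trend removed. Cxcl10 was at 1.21 against 29.3 CPM, Cxcl1 at 20.4 against 93.2 and Ccl7 at 8.01 against 22.7, while Il33, an alarmin, was at 96.6 against 11.6. The chemokine median turned to 0.31 for members at 100 CPM or more and to 0.11 within library-centred sub-cluster 2, where 5 of 9 were higher, and was -1.62 without cluster 18. Of 7 arachnoid markers 6 were lower (median -0.65, percentile 2.0, and -0.87 with the trend removed), but the median was 0.10 within library-centred sub-cluster 2, with 2 of 4 higher, and -2.36 without cluster 18. The lower genes included Aldh1a2 (584 against 974 CPM), Aldh1a1 (424 against 730), Slc22a2 (44.3 against 69.7) and Wnt6.

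Basement membrane genes were higher in fibroblast-like cells of the N-PRα-KO library as measured, and less so with the GC trend removed. Of 15 members 11 were higher, with a median log2 ratio of 0.998 (interval 0.85 to 1.08, percentile 100). With the trend removed the median was 0.24 (percentile 92.3) and 12 of the 15 were higher. Col18a1 was at 483 against 119 CPM, Col4a2 at 2783 against 769, the laminin chains Lama1 at 503 against 169 and Lamc1 at 1406 against 485. The same members had a median of 1.55 in the other classes. All 5 measured pial markers were higher, with a median of 1.50 (percentile 99.9) and 0.61 (percentile 96.5) with the trend removed: S100a6 was at 1810 against 642 CPM and Rdh10 at 267 against 213, and Lama1 and Col18a1 belong to this list too. For the 4 pial markers also measured in several other classes, the median was 1.535 in fibroblast-like cells and 1.975 in those classes. Interstitial collagens had a median of -0.36 (percentile 13.8) and -0.08 with the trend removed, with 3 of 10 higher, 0.004 under the stricter filter, -0.085 within library-centred sub-cluster 1 and -0.925 within library-centred sub-cluster 2, with 2 of 10 higher and -0.73 with the trend removed there. Col1a1 was at 4828 against 9208 CPM and Col16a1 at 61.1 against 95.5, while Col6a1 was at 1458 against 913 and Col6a2 at 1038 against 660. Of 24 matrix glycoproteins and proteoglycans 14 were higher (median 0.31, percentile 98.1, and 0.17 with the trend removed). Spp1, which encodes osteopontin, was at 268 against 38.9 CPM and Fbln2 at 746 against 222, while Ogn was at 165 against 787 and Thbs1 at 28.4 against 98.2. Of 24 matrix remodelling genes 17 were higher (median 0.25, -0.04 with the trend removed and -0.17 under the stricter filter), among them Plau (28.3 against 6.93 CPM) and P4ha2 (22.8 against 8.09).

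Of 9 myofibroblast and contractile genes 7 were higher, with a median of 1.37 (percentile 99.9) and 0.72 with the GC trend removed, but only 2 of the 9 stood over 3 times above their level in other classes of the same library, and these 2 went opposite ways, Cthrc1 at 306 against 529 CPM and Cdh11 at 433 against 202 (median 0.155). Acta2, smooth muscle actin, was at 147 CPM in N-PRα-KO fibroblast-like cells, beside 136 in astrocyte-like, 126 in neuronal-lineage-like and 9942 in mural-like cells of that library, and at 4.24 CPM in WT fibroblast-like cells. Tagln was at 20.9 against 4.24 CPM, Myl9 at 164 against 45.1 and Actn1 at 169 against 62.8, each below 3 times its level in other classes.

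The remaining fibroblast lists had medians from -0.02 to 0.63, with members on both sides of 0, and several changed sign with the GC trend removed. The TGF-beta list had a median of 0.14 (0.21 with the trend removed) with 6 of 11 higher, and held Tgfbi (1038 against 65.5 CPM), Ltbp4 (48.5 against 14.3), Tgfb2 (23.1 against 9.25) and Bambi (14.8 against 40.5). Retinoic acid handling stood at 0.18 (-0.098 with the trend removed) with 5 of 8 higher, with Dhrs3 at 48.4 against 14.3 CPM. Growth factors and the PDGF family stood at 0.23 (-0.20 with the trend removed) with 10 of 19 higher, with Igfbp7 at 460 against 103 CPM, Igfbp5 at 1995 against 592, Pdgfd at 7.86 against 32.4 and Angpt1 at 21.8 against 85.5. Barrier solute transporters stood at -0.02 (0.22 with the trend removed) with 7 of 15 higher, with Slc6a13 at 971 against 203 CPM, Slc2a1 at 86.1 against 13.9, Abcc9 at 40.7 against 8.48 and Slc6a20a at 493 against 1556. Complement stood at 0.32 (-0.21 with the trend removed) with 3 of 5 higher, with C4b at 51.1 against 13.9 CPM, Clu at 354 against 41.6 and Cd55 at 25.1 against 58.2. Clu was at 316 CPM or more in every large class of the N-PRα-KO library. Dural markers had no settled direction, at 0.63 with 3 of 4 higher, 0.16 and 2 of 4 with the trend removed, -1.47 under the stricter filter and -2.58 with each library clustered on its own. The 1 dural member over 3 times its level in other classes was at -2.11. Among these markers were Mgp at 294 against 72.4 CPM and Foxc2 at 23.6 against 102. Perivascular markers stood at 0.16 (0.37 with the trend removed) with 4 of 7 higher, with Col15a1 at 3247 against 1175 CPM, Abca8a at 177 against 61.6 and Gjb6 at 333 against 1113. MHC class I stood at 0.11, hypoxia and glycolysis at 0.20 and the unfolded protein response at 0.06, with 2 of 4, 8 of 12 and 7 of 12 higher. With the trend removed these medians were 0.25, -0.098 and -0.057. B2m was at 401 against 544 CPM, Gapdh at 410 against 87.1 and Calr at 807 against 354. Most of these lists also turned under other settings. Under the stricter filter the medians were -0.80 for TGF-beta, -0.46 for retinoic acid handling, -0.45 for complement, -0.24 for growth factors, -0.29 for MHC class I, -0.13 for hypoxia and glycolysis and -0.62 for the unfolded protein response. Without cluster 18 they were -1.23 for complement, -0.14 for TGF-beta, -0.045 for growth factors and -0.43 for MHC class I. Perivascular markers were at -0.036 with thinned cells and at -0.27 within library-centred sub-cluster 1, where barrier solute transporters were at 0.57.

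**Figure D4:**
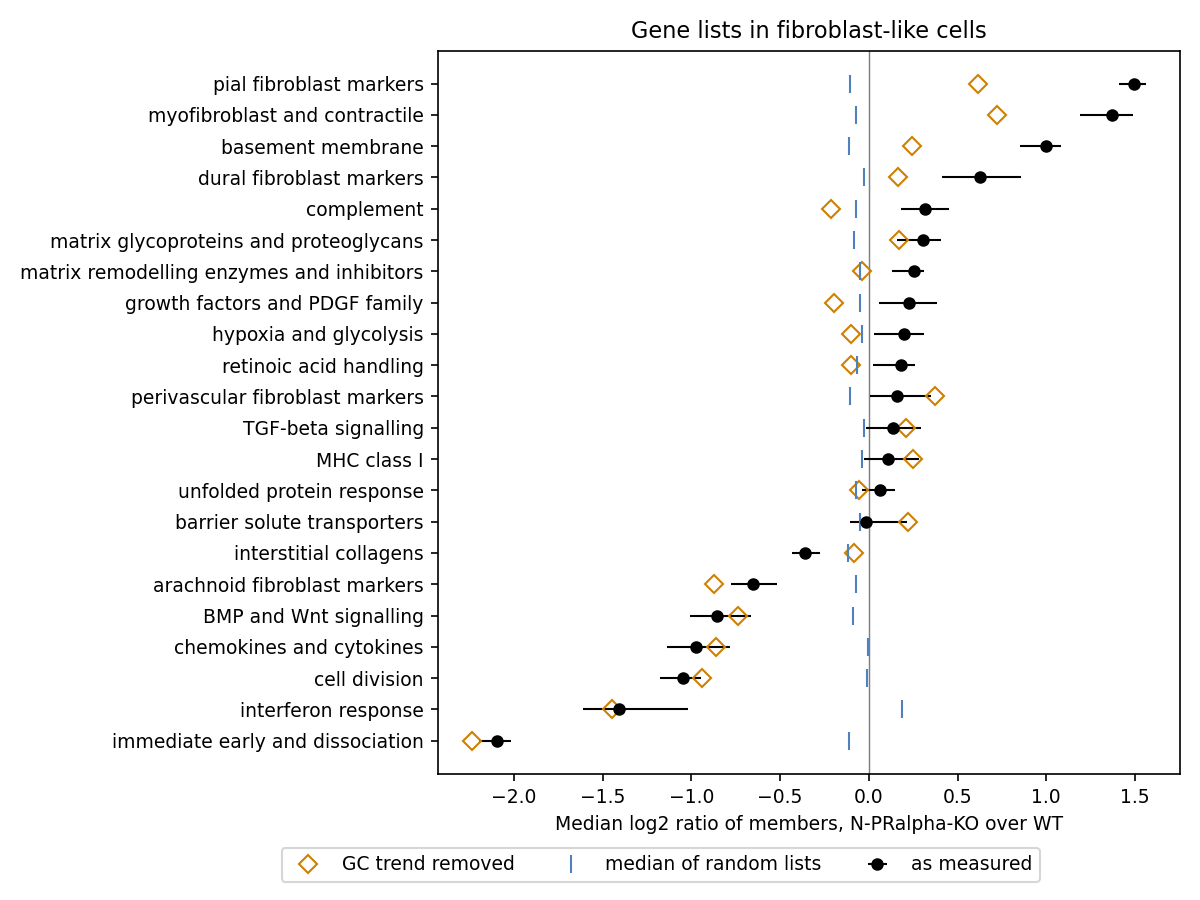
Median log2 ratio of N-PRα-KO over WT for each gene list in fibroblast-like cells (horizontal axis), as measured with its 95% counting interval (black), with the GC trend removed (open diamonds), and for random lists matched on expression (ticks). The immediate early list lies at -2.10 and -2.24 and the basement membrane list at 0.998 and 0.24.

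Among single genes in fibroblast-like cells, the largest ratios toward the N-PRα-KO library included genes that were also higher in other classes. Kif5a, a neuronal kinesin, was at 93.9 CPM (interval 86.6 to 101.5) against 2.31 CPM (0.85 to 5.03), and Bc1, a neuronal noncoding RNA, at 56.7 against 1.54, but their median log2 ratios in the 7 other classes were 2.996 and 4.31, and both were below their level in other classes of that library. Ttr, a choroid plexus product, was at 1723 against 129 CPM and Stim1 at 84.5 against 6.55, with medians of 3.88 and 3.63 elsewhere. Tgfbi, an extracellular matrix protein induced by TGF-beta (chromosome 13, 56609523 to 56639562), was at 1038 CPM (1013 to 1063) against 65.5 CPM (56.0 to 76.1), 24.9 times its level in other classes, and its ratio there was also high at 4.34. Cygb, which encodes cytoglobin (chromosome 11, 116645595 to 116654313), was at 247 CPM (235 to 259) against 10.02 CPM (6.54 to 14.7) and Ajap1 at 244 against 13.9, with log2 ratios of 4.62 and 4.14 and medians elsewhere of 2.18 and 2.62. Nostrin was at 68.9 against 1.93 CPM, Fam163a at 74.4 against 2.31, Meox1, a homeobox gene, at 55.3 against 2.70, Ttyh2 at 78.7 against 5.01 and Kcnn3, a potassium channel, at 65.7 against 4.24, and the median of these 5 elsewhere was at most 0.79, over the 1 to 5 other classes where each was measured.

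The 12 genes with the lowest ratio in fibroblast-like cells were led by Slc5a5, the sodium-iodide symporter, at 4.68 CPM (interval 3.18 to 6.65) in the N-PRα-KO library and 89.4 CPM (78.2 to 101.6) in the WT library. Ptgs2, the inducible cyclooxygenase (chromosome 1, 150100031 to 150108227), was at 7.25 against 126 CPM, Nr4a2 at 8.16 against 117, Coch at 9.52 against 133 and the protease gene Adamts1 at 31.6 against 335. Klf4 was at 96.3 against 990.5 CPM, Hs6st2 at 14.4 against 123, Plscr2 at 10.4 against 67.0 and Fgfbp1 at 21.5 against 136. Fos, Dusp1 and Btg2 complete the 12. Of these 12 genes, 6 also had a median log2 ratio below -1 in the other classes where they were measured. Fos was at -1.50, Btg2 at -1.10 and Dusp1 at -0.44 over the 7 other classes, while Slc5a5 and Coch reached the minimum level in none. All 24 named genes kept a log2 ratio beyond 1 in the same direction with the GC trend removed. They were picked for extreme ratios in these same data, so this is no independent check of them. Under the stricter filter, which left 86 N-PRα-KO and 9 WT fibroblast-like cells, Bc1 and Meox1 had ratios of the opposite sign.

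Clustered on their own, the 1465 fibroblast-like cells formed 7 sub-clusters, and 91.3% of the cells lay in sub-clusters with at least 90% of their cells from 1 library. In the N-PRα-KO library, 51.3% of cells were in sub-cluster 1 (leading genes Fam210b, Cygb, St8sia1, Kcnn3 and Ajap1), 29.4% in sub-cluster 3 (C4b, A2m, H19, Fibin and Ctgf) and 12.4% in sub-cluster 4 (Sulf1, Ptgis, Htra3, Fxyd6 and Il33). In the WT library, 68.9% were in sub-cluster 2 (Fos, Atf3, Klf4, Ptgs2 and Gjb2) and 18.2% in sub-cluster 5 (Fndc1, Gpc3, Emp1, Klf2 and Marcks). Sub-cluster 6, of dividing cells (Top2a, Mki67, Prc1, Ccna2 and Pclaf), held 3.67% and 9.77%, and sub-cluster 7 (Prg4, Dapl1, Egln3, Fn1 and Cdh1) held 3.04% and 2.73%. With 1 library per genotype a sub-cluster of 1 library may be that library, and these shares give no change in composition.

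With genes centred within each library, a choice made after seeing the data, resolution 0.3 gave 4 sub-clusters, each with cells of both libraries. A sub-cluster led by Sidt1, Gjb6, Gjb2, Slc6a20a and Bmp6 held 358 N-PRα-KO and 345 WT cells, and one led by Fam210b, Cygb, St8sia1, Spp1 and Ajap1 held 523 and 96. The others held 44 and 57 dividing cells, and 28 and 14 cells led by Prg4. At resolution 0.5 the same procedure gave 6 sub-clusters, one of them with 201 N-PRα-KO cells and 1 WT cell, so the match between libraries depended on the resolution. Within the first pair of sub-clusters of resolution 0.3, the immediate early list had medians of -1.78 and -2.30 and the basement membrane list 0.62 and 0.55 (0.38 and 0.35 with the GC trend removed).

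Oligodendrocyte-lineage-like cells differed in the makeup of the class as well as in number, with 45 of 67 N-PRα-KO cells in cluster 30 and 2919 of 5058 WT cells in cluster 1. All 14 myelin genes were higher in the N-PRα-KO library, with a median log2 ratio of 3.66 (percentile 100) and 3.37 with the GC trend removed: Mal was at 1740 against 53.5 CPM, Mobp at 3620 against 186, Mog at 779 against 38.6 and Trf, transferrin, at 321 against 8.66. Cluster 26, led by myelin genes, was 13.4% of the 67 N-PRα-KO cells (interval 6.33 to 24.0) and 2.85% of the 5058 WT cells (2.41 to 3.34), and held 239168 of the class's 589236 UMIs in the N-PRα-KO library and 1277158 of 19173792 in the WT library. Without cluster 26, a choice made after the data were seen, the medians were 1.06 for myelin, 0.12 for OPC identity, 0.053 for committed precursor genes, -0.78 for cholesterol synthesis and -0.84 for cell division. Of 14 OPC identity genes 12 were lower (median -0.39, -0.54 with the trend removed and 0.096 with thinned cells), with Ptprz1 at 3050 against 7076 CPM, Lhfpl3 at 1427 against 3086 and Susd5 at 18.7 against 35.8, while Cspg4, which encodes NG2, was at 463 against 215. Of 11 committed precursor genes 8 were higher (median 0.42, and 0.72 with the trend removed), with Myrf at 385 against 88.0 CPM, Enpp6 at 569 against 169 and Bmp4 at 22.1 against 57.9. Of 15 cholesterol synthesis genes 12 were higher (median 0.41, 0.57 with the trend removed and -0.097 with thinned cells), with Hmgcs1 at 888 against 376 CPM. Of 17 cell division genes 16 were lower (median -1.46, and -1.34 with the trend removed), with Rrm2 at 8.49 against 122 CPM and Cenpf at 78.1 against 297. The immediate early list stood at -0.02, the interferon list at 0.53 over 3 genes and MHC class I at 0.56 with all 5 genes higher, and at -0.03, 0.26 and 0.52 with the trend removed. Without cluster 26 the interferon median was -0.26 and the MHC class I median 1.48. The 6 highest single genes were Gamt, Ndrg1, Tmem63a, Tmem151a, Bc1 and Trf, and the 6 lowest were Flrt3, Depdc1a, Mis18a, Knl1, Kif20b and Ampd3, with log2 ratios from 5.78 for Gamt (interval 5.26 to 6.31) to -3.64 for Flrt3 (-5.09 to -2.51). The 6 lowest rest on 6, 2, 3, 6, 7 and 22 N-PRα-KO UMIs in that order, with Depdc1a set to the floor of 3. Of the highest genes 5, and all 6 of the lowest, also had a median beyond 1 in the same direction in other classes. These single genes were not recomputed without cluster 26.

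Microglia-like cells of the N-PRα-KO library had lower levels of all 12 genes on the inflammatory cytokine list, with a median log2 ratio of -2.93 (percentile 0.0) and -2.67 with the GC trend removed. This list also holds Nfkbia, Tnfaip3 and Ptgs2, which do not encode cytokines. Il1a was at 70.0 CPM against 1471 CPM, Cxcl2 at 7.87 against 241 and Ccl2 at 27.0 against 451. Ptgs2 had 3 UMIs in the N-PRα-KO library and 128 in the WT library (log2 ratio -6.17, interval -8.46 to -4.59), and Il1b had 2 and 77 (interval of the log2 ratio -9.09 to -4.12). Outside the list, the chemokine Ccl7 had 3 and 143 UMIs (log2 ratio -6.33, interval -8.62 to -4.75) and Egr3 was at 2.42 against 100.02 CPM. Clusters 7 (534 cells) and 8 (514 cells) held most of the class in the N-PRα-KO and WT libraries. Of 18 immediate early genes 15 were lower (median -1.01, and -1.03 with the trend removed), with Atf3 at 188 against 1532 CPM and Nr4a1 at 63.3 against 425, and of 18 cell division genes 17 were lower (median -1.60, and -1.58 with the trend removed), with Mki67 at 140 against 667 CPM. Homeostatic genes stood at 0.17 (0.24 with the trend removed) with 9 of 13 higher, with Selplg at 657 against 25.004 CPM, Tmem119 at 431 against 98.0, Csf1r at 5291 against 2572 and Gpr34 at 587 against 1136. Disease-associated genes stood at -0.12 (-0.28 with the trend removed) with 5 of 11 higher, with Apoe at 1443 against 603 CPM, Tyrobp at 1428 against 502 and Lpl at 53.9 against 374. The interferon list stood at -0.17 and MHC class I at 0.09 (-0.22 and 0.10 with the trend removed). The neutrophil genes Ngp, S100a9 and S100a8 were at 134, 104.5 and 104.2 CPM in the N-PRα-KO library against 0 UMIs in the WT library. With the WT counts set to the floor of 3 they were 87.4-fold, 68.3-fold and 68.1-fold higher (exact lower limits of the log2 ratio 6.15, 5.79 and 5.78). Cluster 24 of this class, with 33 N-PRα-KO and 126 WT cells, had neutrophil as its second class (score 2.32, after 4.36 for microglia). Which cells held these UMIs was not tested, so other cells within the class cannot be told apart from a change in microglia. Bc1, Uqcr11 and Ftl1 were the other genes with the highest ratios, and their median log2 ratios in the 7 other classes were 4.31, 4.475 and 6.23.

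In endothelial-like cells, most of them in cluster 12 (460 cells) in the N-PRα-KO library and in cluster 19 (279 cells) in the WT library, all 18 cell division genes were lower in the N-PRα-KO library (median -1.56, percentile 0.0, and -1.49 with the GC trend removed), with Pcna at 70.1 against 272 CPM and Rrm2 at 25.4 against 98.3. Blood-brain barrier genes stood at -0.24 (-0.37 with the trend removed) with 6 of 13 higher: Cldn5, a tight junction protein, was at 2819 against 274 CPM, Slc2a1 at 1626 against 588, Slco1a4 at 1147 against 572 and Slc16a1 at 1427 against 3971. Angiogenic genes stood at -0.47 (percentile 10.3) with 2 of 9 higher, and at -0.15 (percentile 44.5) with the trend removed, with Kdr at 1034 against 1875 CPM and Dll4 at 59.1 against 169. Of 3 measured genes of activated endothelium, Vwf was at 220 against 35.2 CPM, Icam1 at 63.6 against 27.9 and Vcam1 at 100.2 against 114 (median 1.19, and 0.71 with the trend removed). The immediate early list stood at -0.41, the interferon list at -0.07 and MHC class I at 0.19, and at -0.54, -0.25 and -0.20 with the trend removed. The highest single genes were Camk2a, Lims2, Vamp8, Kif5a, Uqcr11 and Nrgn and the lowest Cbln2, Tnfrsf11b, Fam111a, Mcm4, Slbp and Cks2. All 6 of the highest genes also had a median log2 ratio above 1 in the other classes where they were measured. Of the 6 lowest, 4 had a median below -1 there. The highest genes stood from 1.25 times (Uqcr11) to 21.8 times (Lims2) their level in other classes of that library, with Camk2a at 1.40 and Kif5a at 1.30 times.

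In the other classes with at least 50 cells in both libraries, many of the genes with the highest ratios recurred between classes. In astrocyte-like cells, held mostly by clusters 14 and 21 in the N-PRα-KO library and by clusters 3, 4 and 20 in the WT library, Arl4d, Txnip, Bc1, Agt, Slc35e4 and Pim3 were highest and Pcdh8, Fgfbp3, Ptx3, Egln3, Fabp7 and Tceal1 lowest. Agt, angiotensinogen, was at 179 against 8.62 CPM and Fabp7, a radial glia and astrocyte fatty acid binding protein, at 1449 against 6451. In ependymal-like cells, held mostly by cluster 11 in the N-PRα-KO library and by cluster 17 in the WT library, Uqcr11, Hint2, Bc1, Camk2a, Kif5a and Ttr were highest and Thbs1, Hs3st1, Cxcr4, Nppc, Plod2 and Hspa1b lowest. In neuronal-lineage-like cells Uqcr11, Bc1, Ttr, Cox4i1, Crip2 and Capns1 were highest and Neurog2, Thap2, Depdc1a, Egr1 and Pcdh8 among the lowest. Neurog2, a neurogenic transcription factor, was at 3.56 against 56.9 CPM. In mural-like cells, with 365 and 54 cells, Ttr, Fxyd1, Lgals1, Crip1, Perp and Cox4i1 were highest and Nr4a2, Dkk2, Cxcl1, Cenpe, Uba6 and B3gnt5 lowest. In ependymal-like, mural-like and neuronal-lineage-like cells, all 6 of the highest genes also had a median log2 ratio above 1 in the other classes. In astrocyte-like cells 5 of the 6 did.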

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

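The settings without the cell filter, with each library clustered on its own and with thinned cells were planned before the data were examined, but the limits used to judge the first 2 were written after the results were seen. The other tests of this part, on the sort, the GC trend and the other classes, were chosen after the results were seen. Unnamed cluster 29, led by Omp and other olfactory genes, held 1.22% of N-PRα-KO cells and no WT cell, and stands here because no comparison of the report used it. Y-linked genes, which were left out of the gene ranking, had 3476 UMIs in the N-PRα-KO library against 275 in the WT library, while Xist had 15129 and 54754, so sex coincides in part with genotype in all comparisons here, and its effect was not tested.

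The first pattern is the small share of oligodendrocyte-lineage-like cells in the N-PRα-KO library. With each library clustered on its own the N-PRα-KO share was 3.13% of the WT share, which argues against joint clustering as the cause. Without the cell filter the N-PRα-KO share was 2.35% of the WT share. In that setting a large cluster stayed unnamed because its cells were shallow, and Scrublet had not worked. Oligodendrocyte-lineage cells among such shallow barcodes could not be named, so this value cannot exclude the filter as part of the cause. A different yield of the CD140a sort cannot be told apart from genotype, since there was 1 sorted library for each, and the share in the main setting was 3.14% of the WT share. Loss of oligodendrocyte precursors after deletion of Pdgfra in the neural lineage stays open as an untested hypothesis.

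The second pattern is the higher level of basement membrane genes in N-PRα-KO fibroblast-like cells. With the GC trend between the libraries removed, the list's percentile among random lists went from 100 to 92.3, inside the range of most random lists, so a GC bias may account for much of it, and the median log2 ratio went from 0.998 to 0.24. Still, 12 of the 15 members were higher with the trend removed, against 11 as measured. The same members had a median of 1.55 in the other classes, but endothelial and mural cells make these proteins and other classes may hold free fibroblast RNA of them, which was not measured. So a shift of the whole library cannot be told apart from a change in fibroblasts. Genotype stays open as untested.

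The third pattern is the lower level of immediate early genes in N-PRα-KO fibroblast-like cells. The median was -2.24 with the GC trend removed, which argues against GC bias as the whole cause. With cells thinned to the same depth it was -2.12. The thinned counts were summed again per library, and random thinning keeps each gene's expected share of a cell's UMIs. The thinned value therefore cannot decide whether depth plays a part. The list was below 0 in 7 of the 7 other classes, although in oligodendrocyte-lineage-like cells 7 of 14 members were lower and the median of -0.02 had an interval from -0.26 to 0.39. So a difference in how the 2 preparations were handled could account for it, and handling cannot be told apart from genotype with 1 library each.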

How the results depend on the processing

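The GC, free RNA, cluster 18, cluster 26, OPC-led sub-cluster and library-centred alternatives were chosen after the data were seen, and the others before the data were examined. A sign change was counted as a reversal only where the interval of the main value left out 0, so lists with a median near 0, such as TGF-beta signalling and MHC class I, could change sign uncounted. By that rule 22 of 23 alternative values for Pdgfra, 310 of 312 for the 24 genes with the highest or lowest ratios in fibroblast-like cells and 485 of 527 for list medians were not reversed. Because the 24 genes were picked for extreme ratios in these same data, a reversal of their sign was unlikely from the start. Single genes named in other classes or from lists were not recomputed under these alternatives. Shares have no direction, so only whether they moved was noted. Of the 44 list medians, 31 had no counted reversal. Only the fibroblast lists were recomputed under other cell filters, with doublet calls kept or under other clusterings. For the other classes the alternatives were TMM scaling, the mean of per-cell CPM, thinned cells, a 5 CPM minimum and the GC trend removed. Oligodendrocyte-lineage lists were also recomputed without cluster 26. How the lists of these other classes depend on the cell filter or the clustering was not examined. TMM scaling shifted the ratios by -0.05 in fibroblast-like and by -0.16 in oligodendrocyte-lineage-like cells on the log2 scale. No paired analysis was possible because each genotype had 1 library. The stricter filter left 9 WT fibroblast-like and 12 N-PRα-KO oligodendrocyte-lineage-like cells. Depth limits the ratios of mural-like cells, for which the WT library held 167620 UMIs in 54 cells. In the planned sub-cluster alternatives, 92.2%, 92.1% and 91.1% of fibroblast-like cells lay in sub-clusters of 1 library at resolution 0.3, at resolution 1 and without the fixed list genes. Without the OPC-led sub-cluster of 14 WT cells, no value moved beyond its counting interval, and the log2 ratio of Pdgfra in fibroblast-like cells was -0.22.

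The values below are log2 ratios or list medians in fibroblast-like cells unless another class or a share is named, and each reversed or moved beyond its counting interval. Moves are given for shares, for Pdgfra and for fibroblast lists at a percentile of at most 1 or at least 99. For all other lists and for single genes only reversals are given. Values not named here may therefore have moved, as the myelin list did without cluster 26. Without the cell filter the values were share of fibroblast-like cells in the N-PRα-KO library 12.9%, share of oligodendrocyte lineage-like cells in the N-PRα-KO library 1.09%, share of oligodendrocyte lineage-like cells in the WT library 46.5%, Pdgfra -0.20, basement membrane 1.14, complement -0.24, pial fibroblast markers 1.60 and cell division -0.92. Under the stricter filter the values were share of fibroblast-like cells in the N-PRα-KO library 17.8%, share of fibroblast-like cells in the WT library 0.528%, share of oligodendrocyte lineage-like cells in the N-PRα-KO library 2.48%, share of oligodendrocyte lineage-like cells in the WT library 47.2%, Pdgfra -0.52, Pdgfra in oligodendrocyte-lineage-like cells -2.06, interstitial collagens 0.004 and basement membrane 0.69. Under the same choice (stricter cell filter), further values were matrix remodelling enzymes and inhibitors -0.17, myofibroblast and contractile 0.73, retinoic acid handling -0.46, BMP and Wnt signalling -1.14, chemokines and cytokines -1.17, complement -0.45, interferon response -1.88 and growth factors and PDGF family -0.24. Under the same choice (stricter cell filter), further values were pial fibroblast markers 0.70, dural fibroblast markers -1.47, immediate early and dissociation -1.67, hypoxia and glycolysis -0.13, cell division -1.47, Bc1 -1.22 and Meox1 -0.11. Without cluster 18 the values were share of fibroblast-like cells in the N-PRα-KO library 15.1%, Pdgfra -0.042, basement membrane 1.09, myofibroblast and contractile 1.50, BMP and Wnt signalling -1.22, chemokines and cytokines -1.62, complement -1.23 and interferon response -2.27. Under the same choice (without cluster 18), further values were growth factors and PDGF family -0.045, pial fibroblast markers 1.81, immediate early and dissociation -2.87 and cell division -0.57. With each library clustered on its own the values were share of fibroblast-like cells in the WT library 6.31%, Pdgfra 0.014, basement membrane 1.12, myofibroblast and contractile 1.04, retinoic acid handling -0.059, chemokines and cytokines -0.71, pial fibroblast markers 1.27 and dural fibroblast markers -2.58. Further values there were immediate early and dissociation -1.83 and cell division -0.83. In that setting the fibroblast-like class held 624 WT cells instead of 512 and 952 N-PRα-KO cells instead of 953, so its values may compare unlike cells. With the mean of per-cell CPM the values were Pdgfra -0.17, Pdgfra in oligodendrocyte-lineage-like cells -0.70, chemokines and cytokines -0.69, perivascular fibroblast markers -0.001 and cholesterol synthesis in oligodendrocyte-lineage-like cells -0.29. With thinned cells the values were Pdgfra -0.19, Pdgfra in oligodendrocyte-lineage-like cells -0.68, basement membrane 0.81, chemokines and cytokines -0.76, perivascular fibroblast markers -0.036, cell division -1.19, OPC identity in oligodendrocyte-lineage-like cells 0.096 and cholesterol synthesis in oligodendrocyte-lineage-like cells -0.097. With TMM scaling the values were Pdgfra in oligodendrocyte-lineage-like cells -1.43. Without cluster 26 the values were Pdgfra in oligodendrocyte-lineage-like cells -0.62, OPC identity in oligodendrocyte-lineage-like cells 0.12 and cholesterol synthesis in oligodendrocyte-lineage-like cells -0.78. With the GC trend removed the values were basement membrane 0.24, matrix remodelling enzymes and inhibitors -0.038, myofibroblast and contractile 0.72, retinoic acid handling -0.098, complement -0.21, growth factors and PDGF family -0.20, pial fibroblast markers 0.61 and immediate early and dissociation -2.24. Under the same choice (GC trend removed), further values were hypoxia and glycolysis -0.098, cell division -0.94 and MHC class I in endothelial-like cells -0.20. With the GC trend of the whole transcript removed the values were basement membrane 0.28, matrix remodelling enzymes and inhibitors -0.064, myofibroblast and contractile 0.97, retinoic acid handling -0.074, BMP and Wnt signalling -1.16, complement -0.042, growth factors and PDGF family -0.24 and pial fibroblast markers 1.01. Further values there were immediate early and dissociation -2.90, hypoxia and glycolysis -0.099 and cell division -0.92. Within library-centred sub-cluster 1 the values were basement membrane 0.62, retinoic acid handling -0.010, BMP and Wnt signalling -0.42, chemokines and cytokines -0.34, interferon response -0.93, growth factors and PDGF family -0.22, pial fibroblast markers 1.15 and perivascular fibroblast markers -0.27. Further values there were immediate early and dissociation -1.78. Within library-centred sub-cluster 2 the values were basement membrane 0.55, myofibroblast and contractile 0.94, retinoic acid handling -0.17, BMP and Wnt signalling -0.56, chemokines and cytokines 0.11, complement -0.62, pial fibroblast markers 0.58 and arachnoid fibroblast markers 0.10. Further values there were immediate early and dissociation -2.30 and cell division -1.63. For list members at 5 CPM or more the values were myofibroblast and contractile 1.099, complement -0.64 and pial fibroblast markers 1.24. For members over 3 times their level in other classes the values were myofibroblast and contractile 0.155, complement -0.20, immediate early and dissociation -2.49 and hypoxia and glycolysis -0.60. For list members at 100 CPM or more the values were BMP and Wnt signalling -1.01 and chemokines and cytokines 0.31. With mitochondrial and ribosomal genes left out of the total the values were chemokines and cytokines -0.46 and complement -0.12. In library-centred clustering at resolution 0.3 the values were share of fibroblast-like cells in sub-clusters of 1 library 0.0%. In library-centred clustering at resolution 0.5 the values were share of fibroblast-like cells in sub-clusters of 1 library 13.8%. Apart from the smaller sets of cells or genes that some settings use, the cause was not tested.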

Other observations

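The tests here were chosen after the data were seen and are given as values only. UMIs of genes from other cell types differed between the libraries in every class. Ttr, made by the choroid plexus, lay between 1524 and 2726 CPM across the 8 large classes of the N-PRα-KO library and between 103 and 165 CPM in the WT library, and the N-PRα-KO library held 39 choroid-plexus-like cells. Ptprz1, an oligodendrocyte precursor and astrocyte gene, was at 66.0 CPM in N-PRα-KO and 281 CPM in WT microglia-like cells. Pdgfra outside its own classes followed the same order, with a median over 6 classes of 25.6 CPM in the N-PRα-KO library and 167 CPM in the WT library.

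In the N-PRα-KO library 44.4% of cells had UMIs of Xist but of no Y-linked gene, 22.9% had Y-linked UMIs without Xist and 14.6% had both. In the WT library these shares were 86.9%, 0.920% and 0.616%. The cell division list was below 0 in all 8 classes compared, from -0.54 in neuronal-lineage-like to -1.60 in microglia-like cells, and at -0.46 and -1.58 there with the GC trend removed. No measured member stood over 3 times above its level in other classes in fibroblast-like or endothelial-like cells. In oligodendrocyte-lineage-like cells 3 of 17 members did, and in microglia-like cells 3 of 18. MHC class I genes had positive medians in the 8 classes, from 0.09 in microglia-like to 1.30 in neuronal-lineage-like cells, and with the GC trend removed these 2 were 0.10 and 1.44 and the endothelial median was -0.20.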
